A study of Mus musculus with 24 samples.

How the data were processed

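The samples were 24 cultures of mouse cells, 2 in each of 12 groups. Per the labels, total RNA was amplified and biotin-labelled, hybridised to Illumina MouseRef-8 v2 BeadChips and read on an iScan, with 1 array per culture and no pooling. The deposited table that is not normalised holds for each array a mean bead signal per probe (intensity), neither background-subtracted nor scaled, and per the file headers a detection p-value for each signal. The submitters' processing notes name BeadStudio 3.2, RMA and lumi without giving their order. The deposited processed values are on the log2 scale, and all arrays share one distribution, which means that the authors normalised them by quantiles. They keep the rank order of the intensity columns and were used as an alternative.

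Intensities were corrected for background and quantile-normalised with limma 3.58.1 (R 4.3.3), function neqc, with an offset of 16 and with the negative controls inferred from the detection p-values, which imply 798 of them. Of 25697 probes, 23978 carried a gene symbol, 0 carried several and 1719 carried none, and symbols were updated through the Entrez ID for 23962. A probe was kept when its detection p was under 0.01 on both arrays of at least 1 group, which left 13848 probes, 13044 of them with a symbol. For each of 9503 genes the probe with the highest mean was used (2526 genes had more than 1). Probes of one gene that gave opposite calls were counted: 3 genes in EpiSC OG2 (Git2, Mta3 and Sall4), 22 in EpiSC lines (Stat3 among them), 21 in ePSC lines, 8 in ePSC-R, 5 in the Cre-treated lines and 6 in MEF, each against ESC OG2, 18 in ePSC lines against MEF and 4 in ePSC-R against ePSC L4. Chromosomes come from the mouse annotation GRCm38.p6. Figures were drawn with matplotlib 3.10.9.

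A linear model of the 12 groups was fitted to all arrays (12 residual degrees of freedom) with limma's lmFit and eBayes, and comparisons are contrasts of group means in which each line counts equally. For ePSC lines against EpiSC lines the 2 arrays of a line were averaged and the 7 lines were the replicates (5 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the 9503 genes, and a gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Differences among lines used limma's moderated F test. A fold against a group in which the gene was not detected on every array was computed after raising undetected values to the lowest normalised value of any detected probe on each array, and is a lower bound.

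Gene lists of 20 kinds were fixed before the data were examined: core pluripotency, ground-state, epiblast, primitive streak and mesendoderm, neuroectoderm, trophoblast and extraembryonic, fibroblast matrix, mesenchymal transcription factors, epithelial junction and keratin, germ line, LIF and Stat3 targets, Nodal and activin targets, FGF and ERK feedback, imprinted, X-inactivation and Y-linked, glycolysis, mitochondrial, S and M phase, cell cycle inhibitors and p53 targets, and DNA methylation. Each was tested with limma's fry, adjusted over 220 tests, and with camera with an estimated correlation between genes. Fry called 167 of the 220 tests and camera 27.

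Named genes followed a rule. For each main comparison they are the 5 largest rises and the 5 largest falls among called genes detected on every array whose values do not overlap between the groups, the 3 genes in each direction with the highest lower bound among those detected in one group alone, and 2 to 4 called members of each list. To these were added Pou5f1, Sox2, Nanog, Klf4, Myc, Zfp42, Fgf5, T, Xist, Dppa3, Cdh1 and Thy1 whatever their value. Other comparisons name the 3 largest rises and falls. Examples were taken from these genes, and T had no matched probe.

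The positions between EpiSC and ESC OG2 are descriptive. Chromosome-wide differences are medians of X-linked or chromosome 10 genes minus the median of the other autosomal genes. Those with an interval cover the genes detected on every array of either side. The bootstrap intervals come from 2000 draws of genes, so they measure the spread between genes and not between cultures or lines.

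The steps were tested on simulated data of 9503 genes. In EpiSC OG2 against ESC OG2, 56.7% of 60 genes shifted 2-fold and 100% of 70 shifted 4-fold were called, with 2 false calls among 9303. For ePSC lines against EpiSC lines the shares were 41.7% at 2-fold, 81.4% at 4-fold and 92.9% at 8-fold, with 5 false calls. The simulated lines of both kinds shared a common spread. In the data, 3550 genes differed among the EpiSC lines and 593 among the ePSC lines (limma F tests). The 5 false calls therefore do not show how often this comparison makes false calls when the EpiSC lines vary more. The F test among 4 lines called 81.7% at 2-fold and 100% at 4-fold, with 1 false call. In the same simulated comparison of EpiSC OG2 and ESC OG2, fry called 10 of 10 shifted lists and 0 of 10 others, as did camera. The simulated genes varied independently and the other lists held no changed genes. The simulation therefore does not show how often fry calls lists of correlated genes. A shift of -0.5 log2 units put on 329 X-linked genes was read as -0.498, and one of 0 as 0.017.

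The counts of called genes, the F tests, the positions, the number of list tests called and the values of named genes were recomputed with an offset of 50, without background correction, with median scaling in place of quantile normalisation, from the authors' processed values, with no filter and with a filter on detection on 12 of the 24 arrays, with the mean of a gene's probes, with the replicate number as a block, with trended and robust eBayes, from the arrays of the compared groups alone, and without each array and, for ePSC lines against EpiSC lines, each line in turn. The array columns name no BeadChips, so a chip could not be used as a block. The chromosome-wide differences, the shares of genes that go with MEF or with raw signal and the comparison of ePSC-RC1 with ePSC-RC2 were computed with the first setting alone.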

Results

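Gene expression was measured on 24 MouseRef-8 v2 BeadChip arrays, 2 for each of 12 groups of mouse cells. The groups were embryonic fibroblasts (MEF), the embryonic stem cell line ESC OG2, and 3 embryo-derived epiblast stem cell (EpiSC) lines, OG2, GOF18 and T9b. Beside these stood 4 EpiSC-like lines, called ePSC L4, L7, C1 and C3, made from MEF with 4 reprogramming factors and grown with LIF and activin. The last 3 groups came from L4: ePSC-R, reverted with a Klf4 virus, and its Cre-treated derivatives ePSC-RC1 and ePSC-RC2. The MEF, ESC OG2 and EpiSC OG2 cells are labelled female. EpiSC OG2 and GOF18 grew as single cells in conditioned medium, and T9b grew on fibroblast feeders in activin-containing medium and was harvested without them. The title of the series concerns the conversion of fibroblasts to the EpiSC state by reprogramming. The replicates are labelled biological, so the p-values measure the spread between these cultures, except for ePSC lines against EpiSC lines, where they measure the spread between lines. The number of arrays, or there of lines, limits the precision.

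Between 9358 and 11415 probes were detected on an array, which was 36.4 to 44.4% of the 25697 on the chip. The median raw signal lay between 125 and 152 on the 6 arrays of MEF, ESC OG2 and EpiSC OG2 and between 81.2 and 107 on the other 18. Correlations between the replicate arrays of a group, across genes, ran from 0.981 to 0.995. On the first component of 9503 genes the ePSC arrays lay at -58.76 to -48.38, the EpiSC arrays at -24.01 to -3.42 and those of ESC OG2 and the reverted lines at 65.42 to 69.67. The fibroblasts stood alone on the second component. On the third, with 10.7% of the variance, the EpiSC arrays lay at 19.14 to 49.19 and the ePSC arrays at -25.21 to -12.93, a range that takes in the arrays of ePSC-R. Across genes, which are not independent replicates, the group means of ePSC lines correlated at 0.976 to 0.992 with each other, at 0.888 to 0.948 with EpiSC lines, at 0.795 to 0.821 with ESC OG2 and at 0.806 to 0.809 with MEF. ESC OG2 correlated with the 3 reverted lines at 0.926 to 0.955. A gene is called higher or lower below at an adjusted p under 0.05 in limma and a change of at least 2-fold. The comparisons, their tests and thresholds, the gene lists and the rule for naming genes were chosen before the data were examined, and later choices are stated as such.

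**Figure D1:**
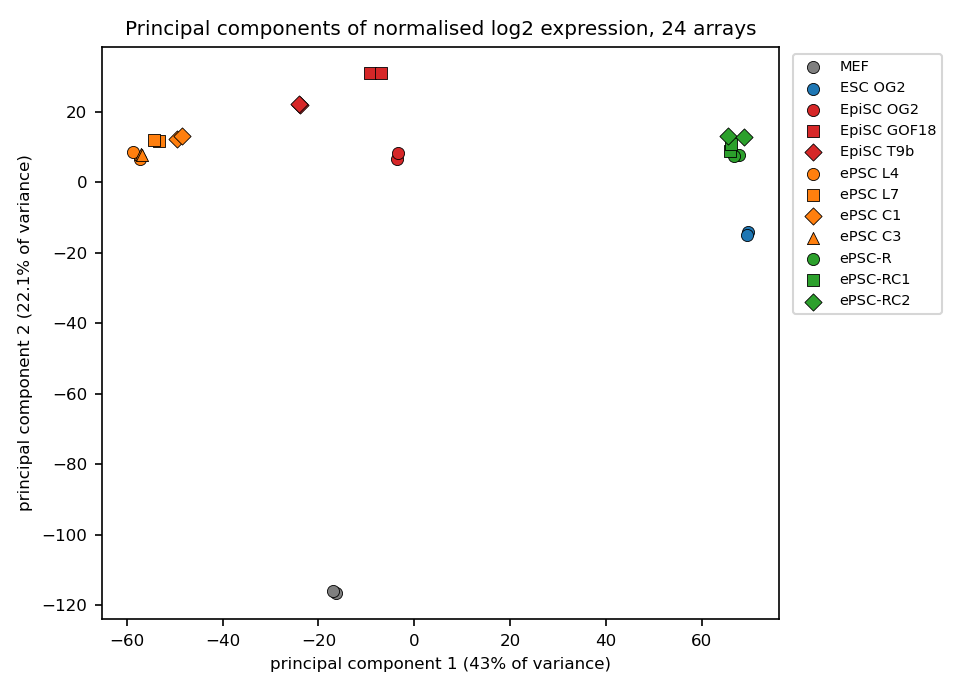
Principal component 1 (43% of the variance) against component 2 (22.1%) of the normalised log2 intensities of 9503 genes, with a point for each of the 24 arrays, coloured by class of cell. The 2 MEF arrays lie apart from the rest, and on component 1 the EpiSC arrays lie between the ePSC arrays and those of ESC OG2 and the reverted lines.

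EpiSC OG2 against ESC OG2 compares the epiblast state with the embryonic stem cell state in cells of one label (2 arrays against 2). The ground-state markers Dppa5a and Esrrb fell at least 667-fold and at least 113-fold in EpiSC OG2. Such bounds apply where a gene was not detected on all arrays of the lower group, whose values were then raised to the lowest normalised value of any detected probe on each array. Fgf5, the classical epiblast growth factor, rose at least 25.4-fold. The chromatin organiser Satb1 had the largest rise among genes detected on every array, 5.25 ± 0.24 (SE) on the log2 scale or 38-fold (adjusted p = 1.96e-12), and Pou3f1, which encodes the POU factor Oct6, rose by 4.56 ± 0.25. Manba, the lysosomal beta-mannosidase, changed most in the other direction, by -6.14 ± 0.20 or 70.5-fold (adjusted p = 1.46e-14).

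Of 9503 genes, 1316 were higher and 1151 lower in EpiSC OG2. The other large rises were those of Car4 (24.6-fold), the X-linked Zcchc18 (19.6-fold) and Psg23 (4.26 log2 units). Anxa2 (34-fold), the TGF-beta family ligand Gdf3 (30.9-fold), Plekha4 (22.2-fold) and the X-linked Porcn (21.2-fold), which encodes an acyltransferase of Wnt proteins, fell. Npy, Chst1 and Slitrk5 were detected in EpiSC OG2 alone of the pair and were at least 76.8-, 53.3- and 35.1-fold higher. Ooep and the chromosome 10 gene Dnmt3l were detected in ESC OG2 alone and were at least 256- and 182-fold lower. Among the regulators of pluripotency fixed in advance, Klf4 fell at least 23.7-fold, Dppa3 at least 11.9-fold and Zfp42 (Rex1) at least 11-fold. Pou5f1 (Oct4), Nanog, Sox2 and Cdh1 (E-cadherin) differed by -0.73 ± 0.19, -0.87 ± 0.15, -0.51 ± 0.20 and -0.23 ± 0.16 log2 units, and Myc by 0.16 ± 0.26. None of these 5 was called. Another Sox2 probe showed a larger fall. It read 10.27 and 10.07 on the arrays of ESC OG2, and 8.87 and 8.51 on those of EpiSC OG2. Xist, the RNA that coats the inactive X chromosome, was undetected in ESC OG2 and at least 4.67-fold higher in EpiSC OG2. The fibroblast marker Thy1 differed by -1.34 log2 units, a call that ended without background correction and with a background offset of 50. T (brachyury) was not measured here.

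Each group of genes below is a list fixed in advance. Its fry test asks whether its measured members moved on balance one way, and compares them with no other genes. The adjusted p given with an estimated correlation between genes comes from camera. Camera asks whether the members moved more than all other genes, so a gap between the 2 values is not an effect of correlation alone. Of 19 measured ground-state genes, 17 fell and 1 rose (fry adjusted p = 2.96e-18; 0.000255 with an estimated correlation between genes). The examples Fbxo15 and Dppa4 fell at least 98.8- and 108-fold. Of 13 germ line genes 12 fell (4.87e-16; 0.000385 with an estimated correlation), among them the X-linked Rhox5 at least 114-fold and Tdrd12 at least 34.2-fold. Of 15 epiblast genes 9 rose and 1 fell (fry adjusted p = 1.43e-11), including Zic2, at least 7.85-fold higher, but the adjusted p was 0.0587 with an estimated correlation. Of 12 LIF and Stat3 targets 7 fell and 1 rose (9.22e-09), with Klf5 at -4.29 log2 units, and the adjusted p was 0.208 with an estimated correlation. Of 25 fibroblast matrix genes 12 fell and 1 rose (1.37e-08; adjusted p = 0.141 with an estimated correlation), led by Acta2, at least 74.7-fold lower, and the X-linked Bgn, at least 13.5-fold lower. Of 11 trophoblast and extraembryonic genes 5 fell (1.18e-10; adjusted p = 0.0629 with an estimated correlation), with Tfap2c at least 58.4-fold lower. Of 6 DNA methylation genes Dnmt3l and Prdm14 fell, the latter with no call without background correction (-0.45) or with an offset of 50 (-0.64), while the de novo methyltransferase gene Dnmt3b rose by 2.27 log2 units (2.16e-09; adjusted p = 0.617 with an estimated correlation). Of 16 genes of cytochrome c oxidase and mitochondrial biogenesis 4 fell (4.82e-05; adjusted p = 0.617 with an estimated correlation), among them the X-linked Cox7b (-2.57) and Cox7a1 (-2.55). The count adjusted over the list alone equalled that over all genes for each of these lists.

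Both X-linked genes and genes of chromosome 10 moved as sets in this comparison. The median change of 265 X-linked genes detected on every array of either group lay 0.71 log2 units under that of autosomal genes (-0.712, interval -0.857 to -0.5), with 89 lower and 35 higher. Over all tested X-linked genes the gap was smaller. Set against ePSC L4, their median minus that of autosomal genes was 0.363 in ESC OG2 and -0.007 in EpiSC OG2. On chromosome 10, 128 of 467 genes were higher and 32 lower. Without background correction 1129 genes were called in place of 2467, and 1434 with an offset of 50. Scaling arrays to one median moved the median of all genes to 0.20 log2 units and gave 1883 higher and 1021 lower.

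Against the mean of the 3 EpiSC lines (6 arrays), ESC OG2 differed in 2781 genes, 1455 higher and 1326 lower in EpiSC lines. Satb1 (22.3-fold), Cd59a (16.9-fold) and Plekhg2 (16.2-fold) had the largest rises, and Manba (29.7-fold), Hspb1 (20.2-fold) and Plekha4 (20-fold) the largest falls. Nanog was called here, at -1.92 ± 0.12 log2 units or 3.78-fold, and so was Klf4, at least 27.2-fold lower. Fgf5 was at least 18.1-fold higher and Zfp42 at least 10.7-fold lower. Cdh1 changed by -1.38, but by -0.92, with no call, without T9b. Pou5f1 (-0.61) was not called, and Sox2 (-0.84) was called when its probes were averaged (-2.15). Median scaling gave 1417 higher and 1439 lower, and 1305 genes were called without background correction and 1637 with an offset of 50.

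MEF against ESC OG2 gives the distance between fibroblasts and stem cells (2 arrays against 2). The collagen gene Col1a1 was 119-fold higher in MEF (6.89 ± 0.25), the receptor gene Axl 82.2-fold and Sprr2k 55.4-fold, and Thy1 was 46.4-fold higher. Dnmt3l (154-fold), the glucose transporter gene Slc2a3 (112-fold) and Upp1 (98.2-fold) were lower. Pou5f1 and Nanog were undetected in MEF, at least 201- and 145-fold lower. In all, 1843 genes were higher and 1774 lower in MEF. Median scaling gave 2374 and 1453, and 2028 genes were called without background correction.

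The ePSC lines against MEF show what differs between the reprogrammed lines and their source cell type (8 arrays of 4 lines against 2). Pou5f1, Nanog and Fgf5, undetected in MEF, were at least 49.9-, 23.1- and 32.9-fold higher in ePSC lines. The Nodal antagonist Lefty1 rose 173-fold (7.44 ± 0.14 log2 units, adjusted p = 9.69e-19), Slc2a3 140-fold (7.13 ± 0.12) and Dnmt3b 115-fold (6.84 ± 0.12). Col1a1 fell at least 184-fold, the collagen crosslinking enzyme gene Lox at least 162-fold and Igfbp7 151-fold (-7.24 ± 0.21, adjusted p = 5.57e-16). Thy1 fell 96.2-fold (-6.59 ± 0.13).

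In total 1753 genes were higher and 1513 lower in ePSC lines. The keratin gene Krt8 rose by 6.68 ± 0.14 log2 units and the activin receptor gene Acvr2b 45.1-fold. Trh, Spink1 and Igfbp2 were at least 251-, 200- and 139-fold higher, with Spink1 lowest in L4 of the 4 lines. Among the falls were those of Loxl1 (125-fold), Ccn4 (-6.71 log2 units) and Bgn (88.8-fold), and Lrrc15, Sprr2k and Gpr176 were undetected in ePSC lines and at least 196-, 92.2- and 90.5-fold lower. Cdh1 was at least 11.8-fold and Sox2 at least 7.68-fold higher. Xist, detected in MEF, was 9.24-fold higher in ePSC lines (3.21 ± 0.17). Klf4 was lower by -1.72 log2 units and Myc at least 2.4-fold. Both calls ended without background correction, that of Myc also with an offset of 50 and that of Klf4 with the mean of its probes (-0.56). Zfp42 (-0.81; -1.80 and called with the authors' values) and Dppa3 (0.03) were not called.

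Of 14 core pluripotency genes 12 rose (fry adjusted p = 4.69e-16; 0.0177 with an estimated correlation), including Sall4, at least 116-fold, and Lin28a, at least 19.7-fold. Of 16 epithelial junction and keratin genes 9 rose (1.76e-16; 0.0189 with an estimated correlation), among them Cldn6, at least 61.1-fold, and Krt18, 23.2-fold. Of 25 fibroblast matrix genes 22 fell (9.63e-16; 0.00855 with an estimated correlation), with Thbs1 at least 73.5-fold lower. Of 13 mesenchymal transcription factor genes 11 fell and 1 rose (8.48e-14; 0.00925 with an estimated correlation), among them Twist2, at least 61.9-fold, Prrx1, at least 17-fold, and Snai1 (-2.74). Of 15 epiblast genes 10 rose and 1 fell (3.29e-15; adjusted p = 0.0556 with an estimated correlation), with Otx2 at least 60.3-fold higher. Of 11 Nodal and activin targets 9 rose and 1 fell (8.48e-14; adjusted p = 0.0953 with an estimated correlation), with Lefty2 at least 29.4-fold higher. Of 17 primitive streak and mesendoderm genes 12 rose (1.3e-12; adjusted p = 0.0709 with an estimated correlation), among them Fgf8, at least 32-fold, Gsc, at least 26.8-fold, and Lhx1, at least 19.8-fold. Of 18 glycolysis genes 9 rose and 2 fell (8.02e-14; adjusted p = 0.0629 with an estimated correlation), with Aldoc at least 11.6-fold and Pdk1 2.41 log2 units higher. Of 13 FGF and ERK feedback genes 4 fell and 1 rose (6.47e-08; adjusted p = 0.351 with an estimated correlation), with Fosl1 at least 4.54-fold lower. Of 16 S and M phase genes 9 rose (2.02e-10; adjusted p = 0.252 with an estimated correlation), such as Mcm3 (1.64), but under median scaling 2 rose and 3 fell (adjusted p = 0.936). Counts adjusted over the list alone were equal for each of these lists.

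These arrays differ in raw signal. Of the 79 named genes called here, 16 also differed the same way between the EpiSC lines on arrays of lower signal (GOF18 and T9b) and higher signal (OG2), among them Trh, Spink1, Krt8, Lefty2, Gsc, Lhx1, Aldoc and Pdk1. The EpiSC lines also differed in medium and as lines, so a gene marked in this way need not follow the signal. Median scaling moved the median of all genes to -0.27 log2 units and gave 1194 higher and 2556 lower. Without background correction 1775 genes were called, and 2114 with an offset of 50.

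**Figure D2:**
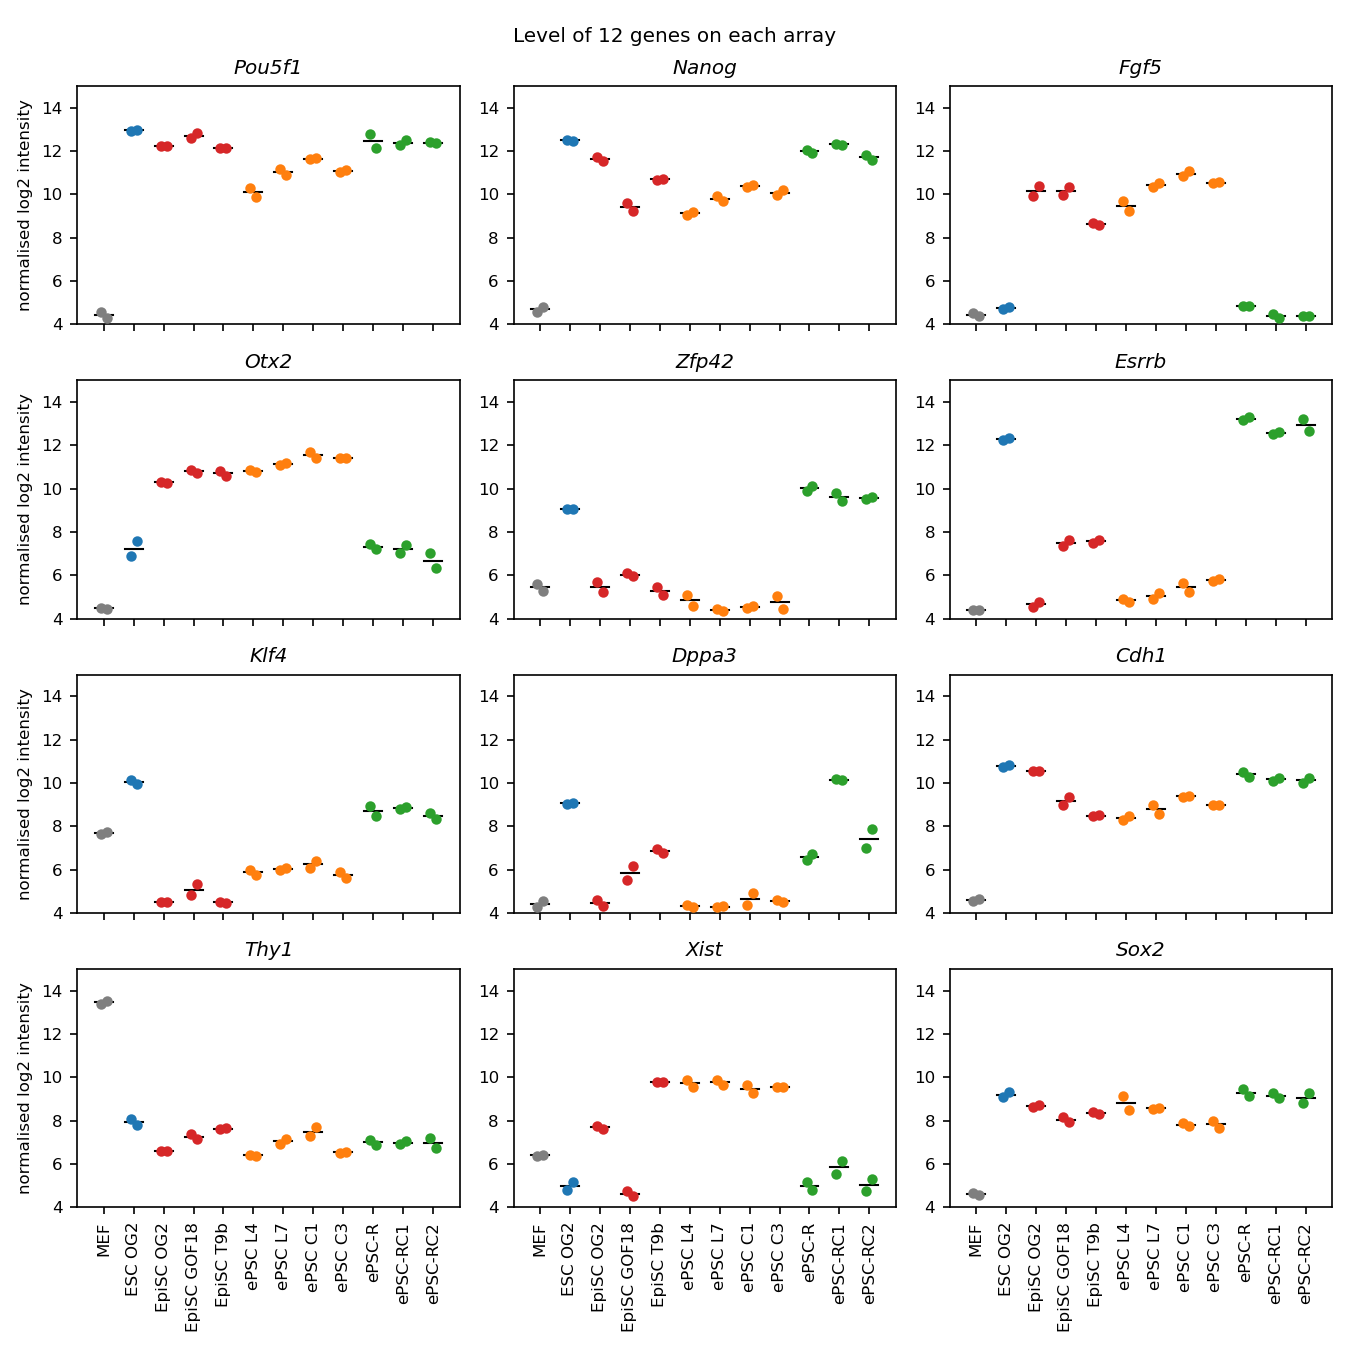
Normalised log2 intensity of 12 genes in the 12 groups, with a point for each array (2 a group) and a line at each group mean, coloured by class of cell. Fgf5 and Otx2 are high in EpiSC and ePSC lines, Zfp42 and Esrrb in ESC OG2 and the reverted lines, and Thy1 in MEF.

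The ePSC lines against the EpiSC lines address how reprogrammed and embryo-derived lines differ, with the line as the replicate (4 lines against 3). The immediate-early gene Fos was 25.1-fold higher in ePSC lines (4.65 ± 0.48 log2 units, adjusted p = 0.0017) and Gadd45g 16.4-fold (4.04 ± 0.45, adjusted p = 0.00234). The neural gene Zic1 was at least 11.7-fold higher and the homeobox gene Lhx1 at least 11.1-fold. Utf1, a chromatin protein of pluripotent cells, was 10.2-fold lower (-3.34 ± 0.49, adjusted p = 0.00637). Nanog (-0.73 ± 0.52), Sox2 (-0.09 ± 0.30, and 0.48 with the mean of its probes) and Fgf5 (0.71 ± 0.47) were not called.

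Of 9503 genes 495 were higher and 215 lower in ePSC lines. Dbx1, Vcam1 and Egr4 were detected in ePSC lines alone of these 7 lines and were at least 8.06-, 5.69- and 5.57-fold higher. Gusb, Shfl and Frrs1 were undetected in ePSC lines and at least 20.4-, 17.3- and 11-fold lower. The chromosome 10 gene Chchd10 (6.65-fold), Fabp3 (5.44-fold) and Cbr3 (4.77-fold) fell. The growth factor gene Igf2 was 29.5-fold higher (4.88 ± 1.09), but its call ended without any 1 of L4, L7, C1, C3 or GOF18 and with no filter. Igfbp5, 22.6-fold higher (4.50 ± 1.19), lost its call without replicate 2 of EpiSC OG2 or of GOF18 or replicate 1 of ePSC C1, at 4.54, 4.58 and 4.46 log2 units, without any 1 of the lines but T9b, and with no background correction, median scaling, no filter or the authors' values. Pou5f1 was 2.65-fold lower (-1.41 ± 0.35, adjusted p = 0.0422), a call that ended without replicate 1 of L4 (-1.46), without any 1 of the lines L4 (-1.12), L7, C3 or GOF18, and with no filter or the authors' values. Klf4 was at least 1.61-fold higher (1.28 log2 units in the fit), at 0.62 with an offset of 50 and 0.45 without background correction, where it was not called. Xist differed by 2.25 ± 1.02 and was called without T9b (3.47), a line with no labelled sex whose arrays showed both Xist (9.79) and the Y-linked Eif2s3y (5.39). Without T9b the EpiSC side is OG2 (7.69) and GOF18 (4.61), and in GOF18 Xist was undetected and Eif2s3y detected. That call therefore cannot be read as a difference between reprogrammed and embryo-derived lines. Zfp42 (-0.95) was not called, but was with the authors' values (-2), without the line OG2 or T9b, and without replicate 2 of EpiSC OG2 (-1.02) or T9b (-1.008) or replicate 1 of ePSC L4 (-1.01) or C3 (-1.03). Dppa3 (-1.27) was called without EpiSC OG2 (-1.90), and both Xist and Dppa3 with arrays as replicates. Cdh1 (-0.52, and 0.05 without EpiSC OG2), Thy1 (-0.29) and Myc (-0.15) were not called.

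Of 7 measured neuroectoderm genes 5 were higher in ePSC lines, or 6 adjusted over the list alone (fry adjusted p = 0.00145; adjusted p = 0.18 with an estimated correlation), including Hes5, at least 3.39-fold. Of 17 primitive streak and mesendoderm genes 7 were higher by either adjustment (0.00256; adjusted p = 0.194 with an estimated correlation), among them Cer1, Gata6 and Sox17, at least 7.62-, 7.42- and 7.38-fold, and Gsc (6.31-fold). Of 12 LIF and Stat3 targets 4 were higher by either adjustment, Fos among them (0.00359; adjusted p = 0.196 with an estimated correlation). Of 14 core pluripotency genes 3 were lower by either adjustment (0.0267; adjusted p = 0.352 with an estimated correlation), Utf1, Pou5f1 and Gdf3 (at least 8.69-fold), the call of Gdf3 ending without any 1 of the ePSC lines or GOF18, with no filter and without background correction. Of 14 cell cycle inhibitors and p53 targets 3 were higher by either adjustment (0.00906; adjusted p = 0.379 with an estimated correlation), such as Cdkn2b, at least 4.88-fold, and Cdkn1a, 2.8-fold. Of 15 imprinted genes 4 were higher and 3 lower, or 5 lower adjusted over the list alone (0.0581), with Nnat at least 7.26-fold lower. Of 16 epithelial genes 2 rose, Krt8 (9.28-fold) and Krt18 (5.55-fold), and 1 fell, or 3 adjusted over the list alone (0.438). Of 25 fibroblast matrix genes 2 were higher, or 7 adjusted over the list alone (0.0617).

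The media of the ePSC and EpiSC lines differed, so medium and origin are not separable in this comparison. The count of 710 genes was 1244 without T9b, 416 without L4, 402 without L7 and 339 without C3, and 439 with an offset of 50 or 331 without background correction; taking the 14 arrays in place of the 7 lines as replicates called 1148, and median scaling, which moved the median of all genes to -0.14, gave 401 higher and 389 lower. Among the 4 ePSC lines 593 genes differed (limma F test), and among the 3 EpiSC lines 3550. Taken 3 at a time, the ePSC lines gave 259 to 556. Without background correction the counts over all lines were 211 and 1615, and with an offset of 50 they were 274 and 2025. The arrays of EpiSC OG2 had the higher raw signal and those of the other EpiSC and the ePSC lines the lower. Between GOF18 with T9b and EpiSC OG2 1943 genes were called. The EpiSC lines also differed in medium, so these counts do not measure how far lines of each kind vary by themselves.

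Against ESC OG2, the ePSC lines (8 arrays against 2) had 1932 genes higher and 1617 lower. Pga5 (89.6-fold), Nrep (75.3-fold) and the imprinted adaptor gene Grb10 (36.7-fold) had the largest rises. Manba (57.3-fold), Laptm5 (50.5-fold) and the small heat shock protein gene Hspb1 (44.3-fold, lowest in L4) had the largest falls. Pou5f1 was 4.03-fold lower (-2.01 ± 0.15), Nanog 6.27-fold (-2.65 ± 0.12) and Klf4 16.8-fold, while Fgf5 and Xist were at least 29.6- and 17.8-fold higher. The other Klf4 probes showed smaller falls than the probe used. Sox2 (-0.94 ± 0.16) was not called, but was under median scaling (-1.18), with the mean of its probes (-1.67) and without replicate 1 of ESC OG2 (-1.06) or of L4 (-1.01). Of 19 ground-state genes 17 were lower (fry adjusted p = 1.57e-18; 0.000385 with an estimated correlation), and of 7 neuroectoderm genes 6 were higher (8.48e-14; 0.0482 with an estimated correlation), the counts adjusted over the list alone being equal. Median scaling, with the median of all genes at -0.10 log2 units, gave 1679 higher and 2044 lower. Nanog, Cdh1 and Pga5 were the 3 of 15 named genes that also differed the same way between EpiSC lines on arrays of lower and higher signal. Without background correction 1893 genes were called, and 2281 with an offset of 50.

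The position of each array between the embryo-derived states was read from the 2781 genes called between EpiSC lines and ESC OG2. In the ePSC lines L4, L7, C1 and C3, 85.5 ± 0.92, 87.9 ± 0.13, 87.5 ± 0.076 and 85.4 ± 0.051% (SD, n = 2) of them lay nearer the EpiSC mean. In ePSC-R, ePSC-RC1 and ePSC-RC2 the share was 42.1 ± 0.33, 34.8 ± 1.2 and 41.5 ± 1.8%. MEF, which belong to neither state, gave 53 ± 0.46%. Raw signal is a limit here, being higher on the arrays of ESC OG2 and lower on those of GOF18, T9b and the reverted lines. With EpiSC OG2 and ESC OG2 alone as ends, both of higher signal, the mean share was 73.5% in ePSC lines and 31.5% in reverted lines. With all EpiSC lines it was 86.6 and 39.5%, so signal and state are not separable in these shares.

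**Figure D3:**
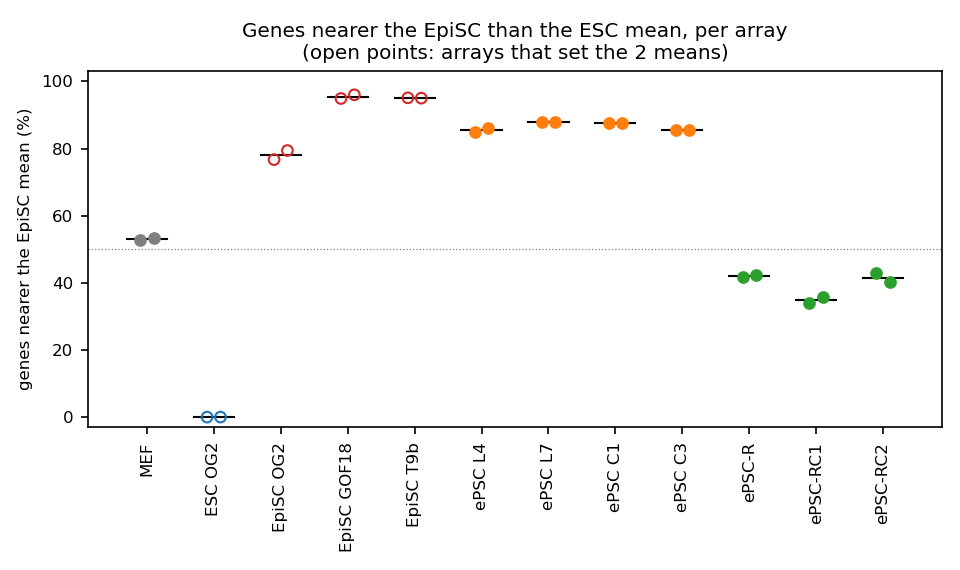
Percent of the 2781 genes called between EpiSC lines and ESC OG2 whose value lies nearer the EpiSC mean, for each of the 24 arrays by group; open points are the arrays that set the means. The 8 ePSC arrays lie between 84.9 and 88% and the 6 arrays of the reverted lines between 33.9 and 42.8%.

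The reverted line ePSC-R against its parent ePSC L4 shows the change that followed Klf4 virus (2 arrays against 2). Dppa5a, undetected in L4, was at least 782-fold higher in ePSC-R, and Esrrb at least 279-fold. Zfp42 rose at least 29.8-fold, Nanog 7.27-fold (2.86 ± 0.15 log2 units) and Pou5f1 5.18-fold (2.37 ± 0.19). Fgf5 and Xist fell to undetected levels, at least 19.9- and 23.4-fold lower. Klf4 itself was 7.08-fold higher (2.82 ± 0.18). The other Klf4 probes rose less. From the arrays of L4 to those of ePSC-R, one went from 5.73 and 5.74 to 7.41 and 7.94. Another went from 6.84 and 6.97 to 9.07 and 9.04. Whether the probes read the viral or the cells' own transcript was not tested.

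In this comparison 1505 genes were higher and 1600 lower. Laptm5 rose 157-fold (7.29 ± 0.15, adjusted p = 1.3e-17), followed by Hspb1 (65.6-fold, with L4 the lowest of the ePSC lines), Fabp3 (51.6-fold), Nupr1 (46.9-fold) and Manba (46.6-fold). The X-linked Xlr4a and Gstp2 appeared, at least 315- and 281-fold higher. Igfbp5 fell 163-fold (-7.35 ± 0.21, adjusted p = 9.31e-16), Spink1 by 6.71 log2 units although L4 was the lowest ePSC line, Pga5 69.6-fold, Nrep 56.7-fold and Igf2 49.7-fold. Ptn, Fgf15 and Irx3 fell to undetected levels, at least 112-, 51.8- and 48.5-fold lower. Cdh1 was 4.07-fold higher. Dppa3 was at least 2.73-fold higher, but not called without background correction (0.92). Sox2 (0.48 ± 0.20), Thy1 (0.59) and Myc (-0.22) were not called.

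Of 19 ground-state genes 17 rose and 1 fell (fry adjusted p = 3.12e-18; 0.000371 with an estimated correlation), with Dppa4 and Fbxo15 at least 188- and 154-fold higher. Of 13 germ line genes 12 rose (1.77e-16; 0.00069 with an estimated correlation), among them the X-linked Rhox5, at least 171-fold, and Dazl, at least 28.1-fold. Of 14 core pluripotency genes 7 rose and 2 fell (3.28e-09; adjusted p = 0.26 with an estimated correlation), Gdf3 being at least 35.1-fold higher. Of 7 neuroectoderm genes 6 fell (8.48e-14; 0.0177 with an estimated correlation), including Zic1, at least 27.6-fold, and Nes, at least 17.2-fold. Of 15 epiblast genes 9 fell (7.01e-12; adjusted p = 0.053 with an estimated correlation), such as Fst (-4.08), Otx2 (-3.49) and Pou3f1 (-3.33). Of 17 primitive streak and mesendoderm genes 8 fell (1.8e-09; adjusted p = 0.128 with an estimated correlation), with Fgf8 at least 27.5-fold and Lhx1 at least 16.8-fold lower. Of 13 FGF and ERK feedback genes 6 fell and 1 rose (1.24e-11; adjusted p = 0.0751 with an estimated correlation), with Egr1 30.4-fold lower. Of 18 glycolysis genes 10 fell, the lactate dehydrogenase gene Ldha by 8.16-fold among them, and Pfkp rose 25-fold (4.06e-10; adjusted p = 0.0953 with an estimated correlation). Of 16 mitochondrial genes 7 rose (3.02e-07; adjusted p = 0.363 with an estimated correlation), including Cox6b2 (2.36), the X-linked Cox7b (2.19) and Esrrb, which is also in the ground-state list. Of the 3 measured genes of the X-inactivation and Y-linked list Xist fell (1.12e-06; adjusted p = 0.617 with an estimated correlation), and the list's median, 0.10, and mean, -1.47, differed in sign. Counts adjusted over the list alone were equal for all of these lists. The median of 295 X-linked genes detected on every array of either line rose against that of autosomal genes by 0.48 log2 units (interval 0.271 to 0.628). Over all tested X-linked genes the rise was 0.411. Median scaling, which moved the median of all genes to -0.15, gave 1137 higher and 1925 lower, and 1622 genes were called without background correction and 1971 with an offset of 50.

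Against ESC OG2, ePSC-R (2 arrays against 2) had 1091 genes higher and 923 lower. The X-linked Magea2 was 22.8-fold higher (4.51 ± 0.21), the calcium pump gene Atp2a3 11.8-fold and Kyat1 10.2-fold. Acta2, the smooth muscle actin gene, was 66.8-fold lower (-6.06 ± 0.15), Spink1 24.3-fold and Lgals1 16.3-fold. Dppa3 was 5.61-fold lower (-2.49 ± 0.25). Klf4 was lower by -1.35, a call that ended with the mean of its probes (-0.12). Pou5f1 and Nanog differed by -0.51 log2 units each, and by -1.18 and -1.12, both called, under median scaling. Zfp42 (0.96) was called without replicate 1 of ePSC-R (1.07), and Sox2 (0.10, and -0.59 with the mean of its probes), Fgf5 (0.08) and Xist (0.01) were not. Of 11 trophoblast and extraembryonic genes 5 were lower, as many as adjusted over the list alone (fry adjusted p = 1.69e-09; 0.0188 with an estimated correlation). Atp2a3 also differed the same way between EpiSC lines on arrays of lower and higher signal. Median scaling, with the median of all genes at -0.12, gave 681 higher and 1481 lower, and 807 genes were called without background correction and 1050 with an offset of 50.

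The Cre-treated lines were compared with ePSC-R, from which they came (2 arrays against 2 each). In ePSC-RC1 the ground-state gene Dppa3 rose 12-fold (3.58 ± 0.25), the intermediate filament gene Vim 9.33-fold (3.22 ± 0.12) and Arhgdib 6.29-fold, and Atp2a3, Aqp3 and Magea2 fell 12.9-, 12.7- and 9.65-fold. In ePSC-RC2 Khdc3 rose 8.67-fold (3.12 ± 0.21), the chromosome 10 gene Aire 5.38-fold and Vim 5.12-fold, and Magea2, Chac1 and Meis2 fell 20.3-, 20.2- and 9.44-fold. Klf4, Nanog and Pou5f1 were not called in either line, at 0.15, 0.32 and -0.08 in ePSC-RC1 and -0.22, -0.26 and -0.08 in ePSC-RC2, Klf4 being at -0.43 in ePSC-RC1 with the mean of its probes. Xist (0.86 in ePSC-RC1) was called there without replicate 1 of ePSC-R (1.02) or of ePSC-RC1 (1.16) and with the authors' values (1.49), and Dppa3 (0.87 in ePSC-RC2) without replicate 2 of ePSC-R (1.008) or replicate 1 of ePSC-RC2 (1.31).

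ePSC-RC1 had 263 genes higher and 609 lower than ePSC-R, and ePSC-RC2 had 169 higher and 477 lower. The replicates of ePSC-RC2 differed most, with a median SD of 0.19 against 0.087 to 0.156 in the other groups. The spread pooled over all groups may therefore understate its noise. From the arrays of ePSC-RC2 and ePSC-R alone 486 genes were called, 117 higher and 369 lower. Of 13 germ line genes 6 were lower and 1 higher in ePSC-RC1 (fry adjusted p = 4.23e-07; 0.0495 with an estimated correlation). Of 14 cell cycle inhibitors and p53 targets 4 were lower in ePSC-RC2 (6.07e-08; 0.0437 with an estimated correlation), and of 18 glycolysis genes 3 were higher (1.54e-07; 0.0469 with an estimated correlation). The median of 269 X-linked genes detected on every array of either line lay below that of autosomal genes in ePSC-RC2 (-0.613, interval -0.728 to -0.548), with 77 lower and 1 higher. Over all tested X-linked genes the gap was smaller. Set against ePSC L4, their median minus that of autosomal genes was 0.411 in ePSC-R and 0.01 in ePSC-RC2. The count of 646 in ePSC-RC2 was 1027 without its replicate 1. Without background correction the counts were 285 in ePSC-RC1 and 180 in ePSC-RC2, with an offset of 50 they were 385 and 248, and with the authors' values 1413 and 1128; median scaling, which moved the median of all genes in ePSC-RC2 to -0.23, gave 147 higher and 668 lower in ePSC-RC1 and 32 and 840 in ePSC-RC2.

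The mean of both Cre-treated lines against ESC OG2 (4 arrays against 2) gives the distance of these lines from embryonic stem cells. Dclk2, a doublecortin-like kinase gene, was 7.14-fold higher in the Cre-treated lines (2.84 ± 0.14 log2 units, adjusted p = 4.31e-11). Acta2 was 24.6-fold lower (-4.62 ± 0.13, adjusted p = 4.6e-14). Pou5f1, Nanog and Cdh1 differed by -0.58, -0.48 and -0.64 and were not called, but under median scaling each was lower and called, at -1.32, -1.16 and -1.24. Sox2 (-0.09), Zfp42 (0.53, and -0.02 under median scaling), Xist (0.46) and Myc (0.05) were not called. Nor was Dppa3 (-0.26), a mean of unlike lines, since its level was 10.14 in ePSC-RC1 and 7.43 in ePSC-RC2 against 9.05 in ESC OG2. Fgf5 (-0.37) was called with the authors' values (-1.19). Thy1 (-0.95) was called under median scaling (-1.53), with the authors' values (-1.08) and without replicate 2 of ESC OG2 (-1.08) or replicate 1 of ePSC-RC2 (-1.05).

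Of 9503 genes 547 were higher and 689 lower. Arrdc4 (6.37-fold), Nlrp4c (5.78-fold), Ivns1abp (5.09-fold) and Fcho1 (4.91-fold) were among the largest rises, and Txnip, Nod1 and Crxos were detected in the Cre-treated lines alone of the pair, at least 24.3-, 10.3- and 7.9-fold higher. Gm428 (16.4-fold), the X-linked Klhl13 (15.6-fold), Spink1 (15.1-fold) and Zfp607a (13.5-fold) were among the largest falls, and Csrp1, BC147527 and Nnmt were at least 14.2-, 7.36- and 6.59-fold lower. Klf4 was lower by -1.39, a call that ended with the mean of its probes (-0.64). Of 15 imprinted genes 6 were lower (fry adjusted p = 1.29e-10; 0.00523 with an estimated correlation), such as the cell cycle inhibitor gene Cdkn1c (4.64-fold). Of 11 trophoblast and extraembryonic genes 4 were lower (8.13e-09; 0.0238 with an estimated correlation), among them Lamb1, at least 2.19-fold, whose call ended without background correction. Of 13 FGF and ERK feedback genes 3 were lower (4.68e-09; adjusted p = 0.0593 with an estimated correlation), with the ERK phosphatase gene Dusp6, on chromosome 10, 4.92-fold lower. Of 25 fibroblast matrix genes 6 were lower (5.29e-07; adjusted p = 0.146 with an estimated correlation), Fbln2 at least 6.9-fold. Of 14 core pluripotency genes 3 were lower (fry adjusted p = 1.22e-05, and 0.208 with an estimated correlation). They were Lin28a (-1.94), Rif1 (at least 2.39-fold) and Tdgf1 (-1.57), and all 3 also differed the same way between EpiSC lines on arrays of lower and higher signal. Of 19 ground-state genes 1 was higher and 2 lower (0.0214; adjusted p = 0.665 with an estimated correlation), a call that ended with the authors' values (adjusted p = 0.304). The count adjusted over the list alone equalled that over all genes for each of these lists.

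All arrays of the Cre-treated lines had a lower raw signal than those of ESC OG2. Of the 61 named genes called, 16 also differed the same way between EpiSC lines on arrays of lower and higher signal, among them Arrdc4, Txnip, Zfp607a, Lamb1, Lin28a and Tdgf1. Without all genes that differed between those EpiSC lines, an alternative chosen after seeing the data, 786 genes were called, 428 higher and 358 lower. This left out 450 of the 1236 called genes, so the count does not test whether the others depend on signal. Median scaling, which moved the median of all genes to -0.31 log2 units, gave 120 higher and 1663 lower; 400 genes were called without background correction, 556 with an offset of 50 and 2067 with the authors' values.

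**Figure D4:**
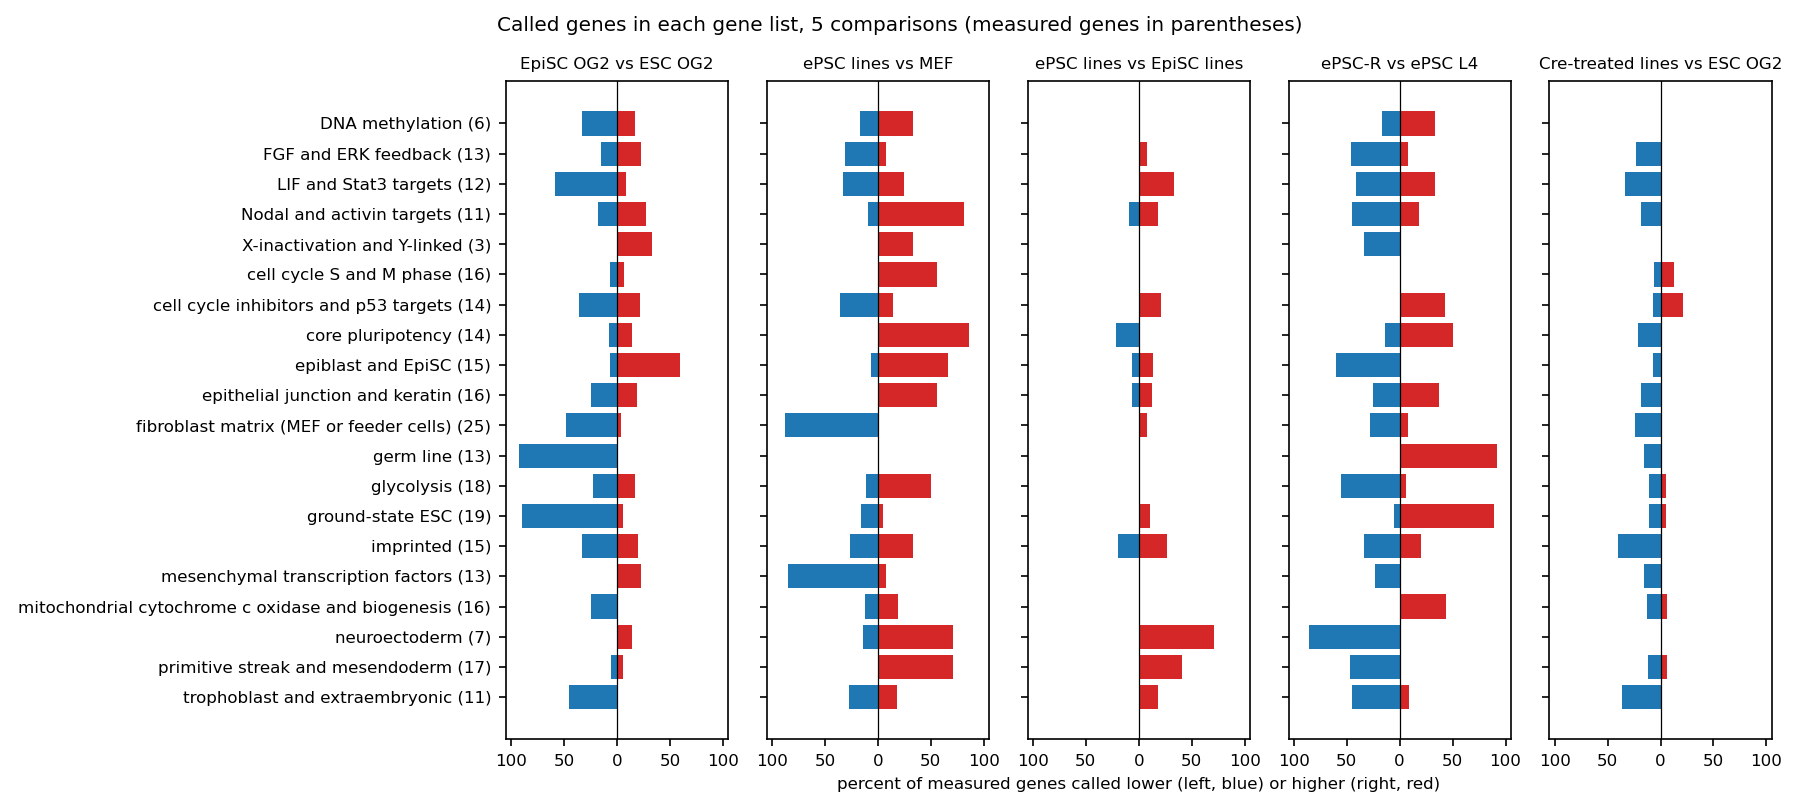
Percent of the measured genes of 20 fixed lists that were called higher (red, to the right) or lower (blue, to the left) in each of 5 comparisons. Ground-state and germ line genes are mostly lower in EpiSC OG2 than in ESC OG2 and mostly higher in ePSC-R than in ePSC L4, and fibroblast matrix genes are mostly lower in ePSC lines than in MEF.

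**Figure D5:**
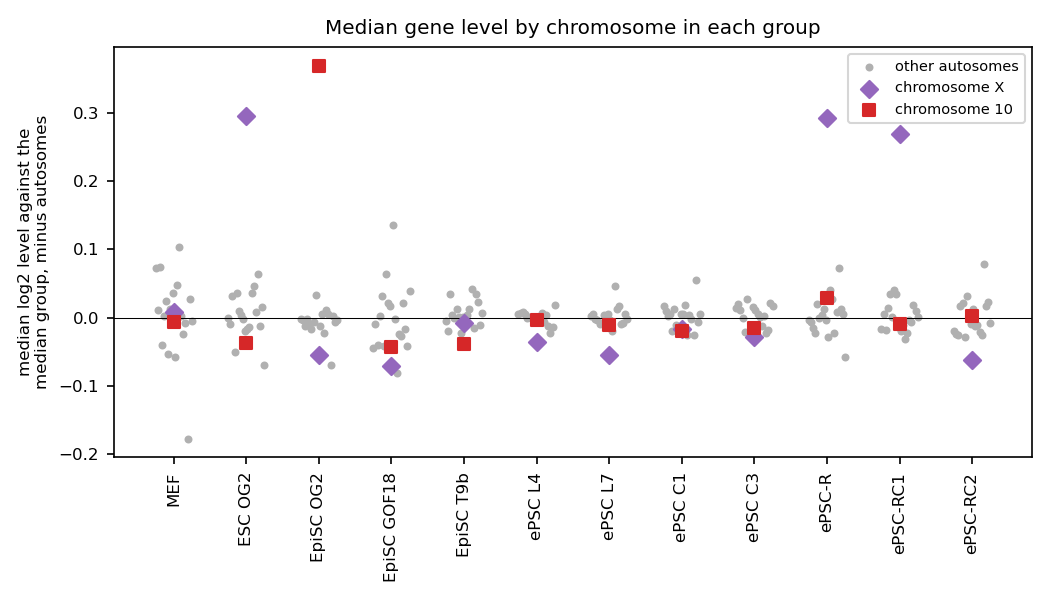
Median log2 level of the genes of each chromosome in each group, against the median group, minus that of autosomal genes. The X chromosome (purple diamonds) lies at 0.295 in ESC OG2, 0.293 in ePSC-R and 0.269 in ePSC-RC1 and near 0 in the other groups, and chromosome 10 (red squares) at 0.369 in EpiSC OG2.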

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

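The tests of array signal and of a shared OG2 background named in this part were chosen after the result was seen.

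Of the 495 genes higher in ePSC lines than in EpiSC lines, 44% were also higher and 9.7% lower in MEF than in ESC OG2. In 1000 random lists matched on mean expression 19.2% (15.8 to 22.8%) were higher. Of the 215 lower genes 11.2% were higher and 46.5% lower in MEF, with 20.5% (15.8 to 26%) higher in random lists. The random lists were not matched on how much genes vary between groups, so a list of more variable genes could exceed them for that reason. A fit without EpiSC OG2, whose arrays had the higher raw signal, called 597 genes higher, 424 of them among the 495, which argues against the raw signal as the whole cause. Of the 35 splits of the 7 lines into 4 and 3, the real one called 710 genes and the highest other 1. Every other split puts ePSC and EpiSC lines together in a group, which widens the spread there and lowers its count. With this and only 35 splits, the comparison of counts cannot exclude chance. The 218 shared genes had a median log2 level of 8.80 in MEF, 8.61 in ePSC lines, 6.42 in EpiSC lines and 5.87 in ESC OG2, with 71 called lower and 41 higher in ePSC lines than in MEF, but of 25 fibroblast matrix genes 22 were lower in ePSC lines, at 0.54 to 20.3% of the MEF signal, and apart from Lum, undetected in MEF, only Mmp2 (86.6%) and Dcn (125%) lay near it. Retained expression of some genes of the fibroblast source is a hypothesis that the 44% fits, and retention of the matrix genes as a whole is not what these values show; the difference in medium, which follows the same split of the lines, is a candidate cause that stays open as untested.

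Of the 1236 genes called between the Cre-treated lines and ESC OG2, 450 were also called between EpiSC lines on arrays of lower and higher raw signal, and 84.2% of these went the same way, where 56% would follow from the higher and lower shares of each comparison. Because both higher-signal groups carry the OG2 label, those genes were also read in ePSC lines against MEF, where neither side is OG2. There 88% of 225 again went with the lower signal (59.4% from the splits). Without this selection it was 71.7% of 897 genes (50% from the splits). Of 43 genes that had gone apart, only 27.9% went with the lower signal there. The 88% may thus partly reflect likeness of this comparison to that of the Cre-treated lines with ESC OG2, and cannot exclude an OG2 background. A technical effect of signal level may account for part of these differences, among them those of Txnip, Arrdc4, Lin28a and Tdgf1, and was not told apart from an OG2 background. For ePSC-R against ESC OG2 the share was 82.4% (52% from the splits), and a biological difference between reverted and embryo-derived cells stays open.

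Among 121 values tested for a line far from the other 3 ePSC lines, 6 were far enough, as many as chance gives at about 1 in 20. They are, in log2 levels, Cdkn2a (5.22), Foxa2 (6.69), Hspb1 (5.92) and Spink1 (12.46), each lowest in L4, Dab2 (6.46), lowest in L7, and Spry4 (5.69), highest in L7.

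The changes from ePSC-R differed between ePSC-RC1 and ePSC-RC2 in 448 genes by limma's test of the difference, 201 higher and 247 lower in ePSC-RC1. X-linked genes made up 60 of these, 59 of them higher in ePSC-RC1 (13.4% of the 448, against 3.46% of all genes). Of the named genes, Dppa3 (2.71 log2 units), Chac1 (2.52), Arhgdib (1.48) and Magea2 (1.08) were higher in ePSC-RC1, and Atp2a3 (-3.36), Khdc3 (-1.79) and Aire (-1.67) were lower. The test behind the 448 genes pools the spread over all groups. That may understate the noise of ePSC-RC2, whose replicates differed most (median SD 0.19). The difference from ESC OG2 varied among the 3 EpiSC lines in 3550 genes and the difference from MEF among the 4 ePSC lines in 593 (limma F tests), which are not on one scale.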

How the results depend on the processing

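The crossed pairing and the settings without chromosome 10, without X-linked genes and without genes of the signal contrast were chosen after seeing the data. The last are genes called between EpiSC lines on arrays of lower and higher raw signal. Counts of called genes are given in the order EpiSC OG2 and EpiSC lines against ESC OG2, ePSC lines against MEF, EpiSC lines and ESC OG2, ePSC-R against ePSC L4 and ESC OG2, ePSC-RC1 and ePSC-RC2 against ePSC-R, Cre-treated lines against ESC OG2, and the F tests among ePSC and among EpiSC lines. An offset of 50 gave 1434, 1637, 2114, 439, 2281, 1971, 1050, 385, 248, 556, 274 and 2025. No background correction gave 1129, 1305, 1775, 331, 1893, 1622, 807, 285, 180, 400, 211 and 1615, and 2028 for MEF against ESC OG2. Both settings compress folds near background, which may account for the lower counts at a 2-fold threshold. The cause was not tested for these or for the other settings. The authors' values gave 1413 and 1128 for ePSC-RC1 and ePSC-RC2 and 2067 for the Cre-treated lines. For ePSC lines against EpiSC lines the count was 1148 from arrays, 416 without L4, 402 without L7, 339 without C3 and 1244 without T9b. The Cre-treated lines against ESC OG2 gave 786 without genes of the signal contrast. Leaving out 1 array moved 1 count by over 1.5 times, ePSC-RC2 against ePSC-R (609 to 1027, the highest without replicate 1 of ePSC-RC2). The mean share nearer EpiSC in ePSC lines was 86.6%, and 89.5, 90 and 83.5% with an offset of 50, no background correction and the authors' values, 73.5% with the axis from OG2 cells and 92% for genes of at least 4-fold; for reverted lines it was 39.5%, 31.5% and 31.4% in the main setting and the last 2. Camera called 27 list tests in place of 167. Other settings stayed within 1.5 times. Crossed pairing gave 649 (ePSC-RC2). Leaving out genes gave 2307 without chromosome 10 (EpiSC OG2) and 568 without X-linked genes (ePSC-RC2). Without genes of the signal contrast the counts were 2369, 2513 and 1362 (ePSC lines against MEF and ESC OG2, ePSC-R against ESC OG2). Leaving genes out takes their calls from a count, so these counts and the 786 do not test the calls that remain. With the replicate number as a block, that is with replicates treated as paired, the 3 counts 2467, 710 and 646 were equal to those without; across the 66 pairs of groups the replicates' deviations correlated at -0.288 to 0.163 (median -0.000742, 2 above 0.1), so the numbers do not pair samples. Of 477 named gene values 374 kept their call, and 356 of these their sign, under each of the 33 to 42 settings that gave them a value (24 that leave out 1 array and, of 22 others, those that apply); the 18 that changed sign were never called. Of 16830 values 243 lost the call, 39 gained it and 0 changed sign with a call. Signal over background limits genes near the detection floor, where folds depend on the background setting.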

Other observations

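The tests of X inactivation and of array signal for the X-linked genes of ePSC-RC2 were chosen after the result was seen.

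The EpiSC lines differed in markers that the means above conceal; these examples were chosen after their values were seen. Esrrb was undetected in EpiSC OG2 and stood at 7.50 ± 0.20 (SD, n = 2) log2 units in GOF18 and 7.56 ± 0.12 in T9b, against 12.3 in ESC OG2, and Dppa4 at 7.66 in GOF18 and 7.10 in T9b. Nanog was highest in EpiSC OG2 (11.62) and lowest in GOF18 (9.41), and Cdh1 ran from 10.55 in OG2 to 8.48 in T9b. Spink1 was undetected in EpiSC OG2, at 8.20 in GOF18 and 10.73 in T9b. Xist was undetected in GOF18 (4.61), and stood at 7.69 in OG2 and 9.79 in T9b. The Y-linked gene Eif2s3y was detected on both arrays of GOF18 (7.73) and of T9b (5.39), and on no array of the other 10 groups. The sex of T9b is not labelled and the line grew on fibroblast feeders; Col1a1, at 13.02 in MEF, was undetected on its arrays, and the source of its Y-linked signal was not tested, so its Xist level and the Xist values that include it cannot be read as those of a line of known sex. The ePSC lines held Xist at 9.46 to 9.76.

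Among the reverted lines Dppa3 stood at 6.56 in ePSC-R, 10.14 in ePSC-RC1 and 7.43 in ePSC-RC2, against 9.05 in ESC OG2. Utf1, at 9.93 in ESC OG2, was at 8.36 in ePSC-R and at 9.82 and 9.97 in the Cre-treated lines. Lefty2 was at 10.63, 11.40 and 11.32 in these 3 lines and 10.71 in ESC OG2.

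Set against ePSC L4, the median of all tested X-linked genes minus that of autosomal genes was 0.41 log2 units in ePSC-R, 0.34 in ePSC-RC1, 0.36 in ESC OG2 and 0.01 in ePSC-RC2, and from -0.045 to 0.062 in the remaining groups. In ePSC-R, where Xist was undetected, 101 of the 295 X-linked genes detected on every array of either group were higher than in L4 and 48 lower. The shift was 0.48, with a lower bound over genes of 0.271, which argues against loss of the inactive X chromosome. It lay above the highest single autosome (0.183, chromosome 16), which argues against array signal. Reactivation of the inactive X chromosome is a hypothesis that fits. The bound measures the spread between genes and not between cultures or lines. In ePSC-RC2 each of 4 equal stretches of X-linked genes detected on every array of either line was lower than in ePSC-R, the least so at -0.573. Xist was undetected in both lines (4.98 in ePSC-R and 5.02 in ePSC-RC2), so its change of 0.04 lies at background. The lowest autosome changed by -0.134 (chromosome 13). Inactivation and array signal are thereby argued against, and loss of one X chromosome may account for the shift, as a hypothesis found and tested on the same data. In EpiSC OG2 chromosome 10 genes were higher than in ESC OG2 by 0.505 (interval 0.378 to 0.606) and by at least 0.364 in each of 4 such stretches, and against MEF, also of high raw signal, by 0.517, which argues against array signal; a gain of chromosome 10 may account for it.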
